A study of Mus musculus with 2 samples.

How the data were processed

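The series measured H3K36me3, the trimethylation of lysine 36 on histone H3 that is laid down along transcribed genes, by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was liver of mouse pups at postnatal day 0, pooled from males and females. The labels give 1 group with 2 biological replicates. Replicate 1 was a pool of livers from 15 pups and went into the peak calling as a single technical replicate. Replicate 2 was another pool of pups and went in as a pair of technical replicates. No other tissue, age or treatment was compared.

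The files used were 4 peak lists on the mouse build mm10 (GRCm38). Each replicate had its own list, called by the authors on the alignments of that replicate alone, per the file headers and descriptions deposited beside them. A pooled list was called on the alignments of both replicates, and a replicated list was derived from the 3 others. Each single list and the pooled list also drew on a pair of further input files whose content the descriptions do not name. The peak caller, its version, its thresholds, the aligner and the filters are not given in the sources used here.

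Each peak in the deposited lists has a fold enrichment, which is a linear ratio over the background that the authors' caller used. Each peak also has a deposited −log10 p-value and a deposited −log10 q-value. These values per peak are the authors' and were used only to describe, rank or filter peaks within a list. The largest p-value in the lists was 0.0098 in replicate 1 and 0.0093 in replicate 2. The lists hold no read counts, so sequencing depth is unknown, and a base without a peak is a base without a call, not a base without the mark.

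The replicate 1 list held 195444 peaks over 75.2 Mb, or 2.84% of the sequenced genome, and the replicate 2 list held 234044 peaks over 88.5 Mb, or 3.34%. The pooled list held 194768 peaks and the replicated list 136265. No peak ran past the end of a chromosome. Every one of the 136259 replicated peaks on chromosomes 1 to 19, X and Y was also a peak of the pooled list. Of these, 114561 (84.1%) touched a peak in both replicate lists and 21698 (15.9%) did not, so the replicated list is not the plain overlap of the replicate lists.

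Genes came from GENCODE M21 on GRCm38, with 55413 genes on these chromosomes and 21221 protein-coding genes of at least 1 kb. Exons were those of the basic transcript set, and introns were the rest of each gene body. Chromosome lengths, G+C content and repeat-masked bases came from the GRCm38 genome sequence. The covered share of a gene is the percentage of its body, from annotated start to annotated end, that lies in peaks. A gene was called marked when the covered share was at least 20% in each replicate. Genes that share bases, such as nested genes and readthrough loci, share peaks too, because the assay has no strand: 387 of the marked genes had over 50% of their body inside another protein-coding gene.

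The peak lists were compared by overlap, with a peak counted as shared when at least 50% of its length lay in the other list. The overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and bedtools 2.31.1 gave the same counts of shared peaks, 118112 for replicate 1 and 110967 for replicate 2. Chance levels came from 100 rotations, in which all peaks of a chromosome were moved by a random offset along it. Shares of peaks have 95% Wilson intervals, which cover counting error only. Means over the replicates are given ± SD with n = 2, a spread between 2 pools of animals.

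Gene lists were tested by the median covered share of their members, averaged over the replicates, against 10000 random lists of protein-coding genes matched on gene length in 20 bins. This is a two-sided permutation test with a smallest possible p of 2.000e-04, adjusted over 34 lists by the method of Benjamini and Hochberg. Its p-values describe these 2 pools, because genes are not replicates. The lists comprised 29 sets of symbols and 5 classes taken by symbol. Of 507 symbols, 505 matched the annotation, 1 of them through a synonym. The symbol pattern of the ribosomal protein class had first taken in Rps19bp1 and Rps27rt, which were removed after values were seen. Lists overlap in places: Alas2 is in the erythroid and heme synthesis lists, and Hmbs is in the heme synthesis and housekeeping lists. Exons and introns were compared within marked genes with at least 3 exons by a sign-flip permutation test over genes with 100000 draws. The X chromosome was compared with the autosomes by Fisher's exact test (scipy 1.17.1), which treats genes as units. The figures were drawn with matplotlib 3.10.9.

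The groups, main tests, fixed gene lists, thresholds and most alternatives were set before the data were examined, and what was chosen or changed later is named as such where it is used. Also set before was the rule for the genes named: the members of each list with the highest and the lowest covered share, the 10 genes with the most bases covered in both replicates and the 10 with the highest covered share, the 5 genes that differed most each way between the replicates, the 5 longest stretches of replicated peaks outside genes, all 8 globin genes, Xist, and the 10 replicated peaks with the highest fold enrichment. Genes named outside this rule are said to have been chosen after their values were seen.

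The computations were tested on simulated data made of rotated peaks with 200 genes covered on purpose. Every planted gene was called marked, both at a planted share of 30% and at 60%, while 0.428% of the 21021 other genes were. The list test found 100% of the lists of planted genes, which held covered genes only, and gave p under 0.05 for 1% of 100 lists of unplanted genes. The 1% belongs to this sparse background and need not hold in the data, where 23.1% of genes were marked. The alternatives were a q-value of 0.01 or lower, other overlap and coverage minimums, equal numbers of top peaks, joined peaks, the replicated list, the 3′ part of genes, other gene sets and each replicate alone.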

Results

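H3K36me3 was profiled by ChIP-seq in newborn mouse liver, an organ that holds hepatocytes and, at birth, blood-forming cells as well. There was 1 group, with 2 biological replicates that were each a pool of livers from several pups. The questions the design allows are where the mark lay, over which genes, and how closely the pools matched. The replicate lists held 195444 and 234044 peaks with a median width of 277 and 262 bases and a median fold enrichment of 3.68 and 3.63. Read depth is unknown, so no value below has an interval from read counts. All coordinates are on GRCm38, and values per gene are covered shares, the percentage of the gene body in peaks.

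The first comparison was between the peak lists of the replicates. The replicated list, which was derived from both replicates, had its highest fold enrichment in Zfp207 (chromosome 11, 80388215 to 80390416, 11.9), followed by peaks in Tfrc, the transferrin receptor gene (chromosome 16, 32618409 to 32621741, 11.7), and Wdr26 (chromosome 1, 181197543 to 181199069, 11.5). Others of the 10 highest lay in Eif2ak1, which encodes the heme-regulated kinase of red cell precursors, in Car2, in St3gal5, in the splicing factor gene Srrm2 and in Top2a. Over the whole genome the lists shared 48.9 Mb, which was 42.6% of the bases in either list, against 1.77% after rotation of one list.

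Of the replicate 1 peaks, 60.4% (60.2 to 60.7) were shared with replicate 2, and of the replicate 2 peaks 47.4% (47.2 to 47.6) were shared with replicate 1. Rotated lists gave 3.73% and 3.20%. The shared part fell with peak strength. Among the 10 equal parts of each list ranked by the authors' p-value, it was 93.0% for replicate 1 and 86.9% for replicate 2 in the strongest part, and 41.1% and 26.2% in the weakest. The shared percentages depend on the minimum overlap, and with 1 shared base they were 73.7% and 61.0%.

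**Figure D1:**
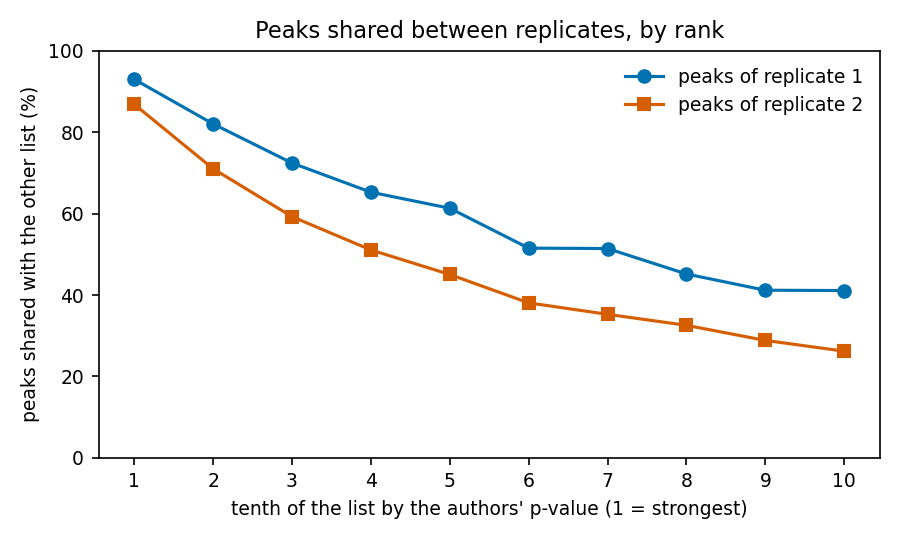
Percentage of the peaks of each replicate with at least 50% of their length in the other replicate's list (vertical axis), for 10 equal parts of the list ranked by the authors' p-value (horizontal axis, 1 is the strongest); each point is a part of a list. The values fall from 93.0% to 41.1% for replicate 1 and from 86.9% to 26.2% for replicate 2.

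The second comparison set the position of the peaks against the annotation. Nearly all of the marked DNA lay in gene bodies: 96.7% ± 0.178 (SD, n = 2) of peak bases, against 48.7% after rotation. Introns held 77.9% ± 0.373 of peak bases, and exons 18.7% ± 0.552, which was 4.44 times the rotated share of 4.22%. The surroundings of transcription start sites were avoided. Within 1 kb of a start site lay 0.353% ± 0.0116 of peak bases, against 1.69% after rotation, whereas within 1 kb of a transcript end lay 6.80% ± 0.0595, against 1.697%. Outside all genes lay 3.35% ± 0.178, against 51.3%. These differences were many times the SD between the replicates and lay outside the range of the 100 rotations.

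Stretches of replicated peaks far from any annotated gene were few. Of 20814 stretches made by joining peaks within 3 kb, 64 lay at least 5 kb from every gene, and they added up to 0.0448 Mb. The longest, of 6.75 kb, lay on chromosome 1 (127711705 to 127718453), 11 kb from Acmsd. The next, of 6.01 kb, lay on the Y chromosome (90735591 to 90741596), where replicate 1 covered 49.4% of it and replicate 2 61.7%. The other 3 of the 5 longest lay on chromosome 5 (104582233 to 104585415), chromosome 18 (4410491 to 4413092) and chromosome 3 (27087548 to 27089844), the last 7.4 kb from Ect2.

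The third comparison followed the mark along 4520 marked genes of at least 5 kb. Peaks were almost absent from the 5′ end and dense towards the 3′ end. Peaks covered 5.23% ± 0.905 (SD, n = 2) of the first of 10 equal parts of the gene body, 33.1% ± 3.75 of the third, 52.0% ± 4.15 of the sixth and 58.0% ± 3.73 of the ninth, and 52.1% ± 3.92 of the last. The kilobase upstream of the start had 1.06% ± 0.142. Past the annotated end the mark ran on, with 35.99% ± 3.99 in the first kilobase, and fell to 13.4% ± 1.54 in the fifth. The fifth kilobase upstream of the start had 10.6% ± 1.05. Flanks were not cleared of neighbouring genes, so their outer values can hold peaks of those genes. The last part exceeded the first by 46.8 ± 3.02 percentage points, by 44.7 in replicate 1 and 48.97 in replicate 2. In the 13278 other genes of at least 5 kb the covered share was 0.852% ± 0.196 in the first part and 7.30% ± 0.978 in the last. Over all protein-coding genes of this length, marked or not, the difference between the last and the first part was 16.7 percentage points.

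**Figure D2:**
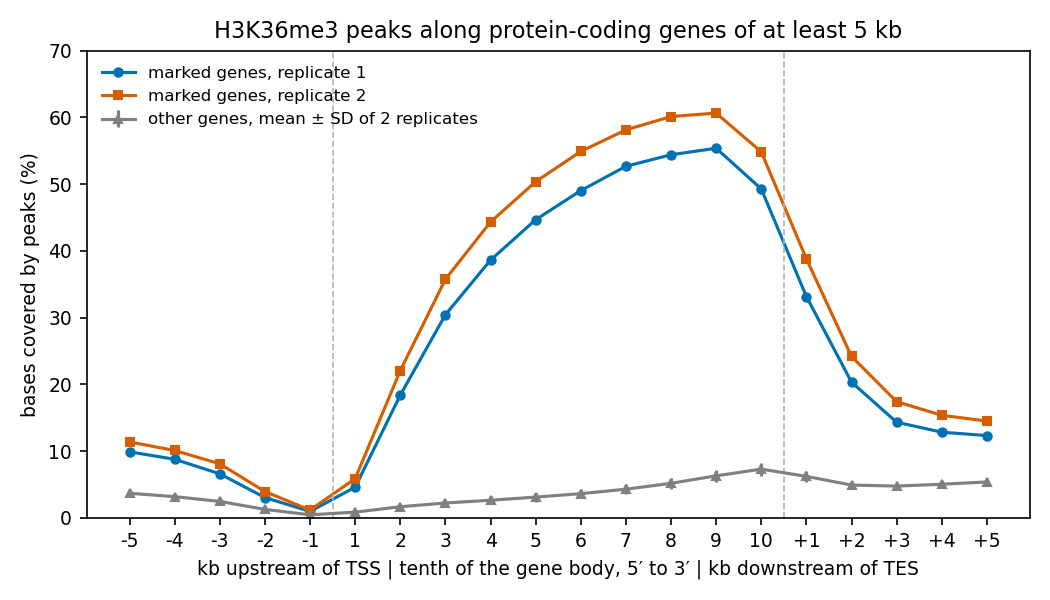
Percentage of bases covered by peaks (vertical axis) in 5 upstream kilobases, 10 equal parts of the gene body and 5 downstream kilobases (horizontal axis), for marked genes in each replicate and for other genes as the mean with SD of the 2 replicates. In marked genes the mean of the replicates is 5.23% in the first part, 58.0% in the ninth and 35.99% in the first kilobase past the end.

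The fourth comparison was made within genes, between exons and introns. Internal exons were more covered than the introns of the same genes. The first and last exons were left out, but all introns were kept. The first intron starts near the 5′ end, where peaks were sparse, so position can add to the difference over whole genes. Over 4792 marked genes the mean was 60.7% ± 3.36 (SD, n = 2) for exons and 40.05% ± 3.53 for introns, a difference of 20.6 ± 0.176 percentage points. Exons were the more covered in 3944 of the genes in replicate 1 and in 3958 in replicate 2. The two-sided sign-flip permutation test over genes gave p = 1.000e-05 in each replicate, the smallest it can give. In the 3′ 50% of the gene body, where both were dense, exons of 4457 genes had 71.6% ± 3.74 and introns 55.8% ± 3.98, and the difference was 15.8 ± 0.233 percentage points.

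The fifth question was which genes carried the mark. By the rule of at least 20% in each replicate, 4902 of 21221 protein-coding genes (23.1%) were marked, while 9237 (43.5%) had no peak base in either replicate. The highest covered shares were those of the uridylyltransferase gene Tut7 (87.4% ± 4.34, SD, n = 2), the splicing factor gene Sf1 (86.5% ± 4.22), Leng8 (84.8% ± 3.15), the phosphate transporter gene Slc20a1 (84.7% ± 3.80) and the DNA topoisomerase gene Top2a (84.4% ± 4.32). They were followed by Rbm5, Hnrnpul1, Atg4d, the nuclear import gene Kpnb1 and Gigyf1, which lies wholly inside another annotated coding gene. By bases covered in both replicates, the ubiquitin ligase gene Ubr4 had 87.2 kb of its 137 kb, Hectd4 81.7 kb, the chromatin remodeler gene Chd2 72.5 kb and Rnf213 71.2 kb. Vps13d, Herc1, Macf1 and Fryl had 66.6, 65.8, 61.6 and 60.7 kb. Gm20388 (274 kb) and Fgfr2 (84.4 kb) also belong to these 10, but their annotated spans of 4435 kb and 2961 kb contain many other genes, and their covered shares were 9.84% and 5.38%. With a minimum of 40% the number of marked genes was 2073.

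Gene length bore on the call. When genes were ranked by length and split into 10 equal parts, 8.11% of the shortest (1 to 3.53 kb), 34.2% of those between 26.2 and 38.0 kb and 4.52% of those above 113 kb were marked. The gene list tests were therefore matched on length.

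Genes of proliferation carried the mark along most of their length. Of 24 cell cycle genes, 23 were marked, with a median covered share of 66.9% against 3.15% in random lists of matched length. Top2a (chromosome 11, 98992943 to 99024189) had 84.4% ± 4.32 (SD, n = 2), the mitotic kinase genes Cdk1 and Aurka had 78.8% ± 5.68 and 75.9% ± 7.81, and the lowest marked members were Bub1 (35.6% ± 2.49) and Tyms (45.7% ± 0.734). The exception was the X-linked DNA polymerase gene Pola1, at 1.02% ± 0.162. Housekeeping genes (19 of 23 marked, median 44.2%), genes for writers, erasers and readers of H3K36 methylation (15 of 22, 40.4%) and ribosomal protein genes (55 of 76, 40.2%) were covered as well. Examples were the elongation factor gene Eef2 (70.6% ± 1.00), the chaperone gene Hsp90ab1 (67.8% ± 1.92), the reader gene Glyr1 (77.3% ± 1.25) and the demethylase gene Kdm4a (72.1% ± 0.103). Low members were Eef1a1 (9.47% ± 1.48), Hprt (15.1% ± 7.57), Dnmt3b (7.82% ± 2.00) and Kdm2b (5.18% ± 0.679). Pgk1 and Ubc, chosen after their values were seen, were the other unmarked housekeeping genes. Each of these 4 lists had an adjusted permutation p of 9.713e-04, which is the smallest the test could give here.

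Most of the listed erythroid and heme synthesis genes were marked too. Which cells of the liver carried the mark on them was not tested. Of 25 erythroid genes, 18 were marked (median 31.4% against 2.79% in random lists), led by Tfrc (75.5% ± 0.708), the anion exchanger gene Slc4a1 (67.7% ± 11.1) and the erythropoietin receptor gene Epor (50.95% ± 12.2). The lowest were Tspo2 (11.1% ± 15.7), Bcl11a (4.85% ± 0.257) and the X-linked Gata1 (2.42% ± 3.42), the master transcription factor of the red cell lineage. Of 14 heme synthesis genes, 12 were marked (median 52.7%), with Ppox at 73.7% ± 1.69 and Abcb10, which lies inside another coding gene, at 66.7% ± 6.75. The unmarked members were Cpox (16.0% ± 0.399) and the X-linked Abcb7 (0.685% ± 0.394). Both lists had an adjusted permutation p of 9.713e-04. The globin genes had no peak base in either replicate in any of the 8 (Hba-a1, Hba-a2, Hba-x, Hbb-bt, Hbb-bs, Hbb-bh1, Hbb-bh2 and Hbb-y). They measure between 0.81 and 1.72 kb, and the 6 of at least 1 kb gave an adjusted permutation p of 1.

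Genes of liver function were covered unevenly. Among these lists, fatty acid oxidation and ketogenesis alone passed the threshold (adjusted permutation p = 0.0051). Whether hepatocytes or other cells carried the mark on its genes was not tested. The list had 13 of 19 marked and a median of 34.5% against 4.37% in random lists. Acadvl (57.9% ± 2.22), which overlaps a neighbouring gene over 40.5% of its body, Acsl1 (55.2% ± 5.49) and Hadha (54.1% ± 2.44), all enzymes of fatty acid breakdown, led it, while the regulators Ppara (8.34% ± 0.723) and Ppargc1a (2.82% ± 0.0436) and the hormone gene Fgf21 (0%) were lowest. Secreted plasma proteins had 6 of 21 marked (median 9.07% against 0.645% in random lists, adjusted permutation p = 0.573). The transferrin gene Trf, which lies inside another coding gene, had 28.2% ± 1.74, Itih3 26.5% ± 7.50 and Apob 25.0% ± 2.76. Apoh had 3.42% ± 0.0746, Vtn 0.356% ± 0.503 and Apoc3 0%. Albumin (Alb, 4.70% ± 2.32) and alpha-fetoprotein (Afp, 10.9% ± 0.708), chosen after their values were seen, were not marked either.

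Of the complement and coagulation genes, 3 of 22 were marked, namely C3 (56.4% ± 0.111), F10 (31.6% ± 2.16) and Cfb (28.4% ± 4.37), the last inside another coding gene. C4bp, C6 and F9 had 0%. The list had a median of 7.89%, against 4.75% in random lists, and an adjusted permutation p of 1. Amino acid and glucose metabolism had 4 of 20 marked (median 11.8% against 4.86% in random lists, adjusted permutation p = 0.787). These were the urea cycle genes Ass1 (42.4% ± 5.07), Asl (39.0% ± 2.91) and Arg1 (33.8% ± 5.10), and Fah, chosen after its value was seen (21.02% ± 1.01). Tdo2 had 0%, the X-linked Otc 0.113% ± 0.160 and the glucokinase gene Gck 1.42% ± 0.294. Among transporters, Abcb4 (45.2% ± 4.59) and the bile acid carrier gene Slc10a1 (45.1% ± 0.451) were marked, and the next was Abcc2 (14.003% ± 1.97). Abcc3, Slc22a1 and Slco1a1 had 0% (list median 8.20% against 6.42% in random lists, adjusted permutation p = 1). None of the 18 cytochrome P450 and bile acid genes was marked. The highest were Cyp2d26 (17.2% ± 6.14) and Cyp39a1 (15.4% ± 0.928). Cyp1a2, Cyp2b10 and Cyp2c29 had 0% (list median 2.57% against 2.58% in random lists, adjusted permutation p = 1). Of 17 liver transcription factors, Nr1i3 was marked (24.2% ± 2.49, 69.7% of it inside another coding gene). Rxra had 14.2% ± 1.08, Hnf4a 9.88% ± 1.02, and Cebpa, Cebpb and Foxa1 0% (list median 3.99% against 1.09% in random lists, adjusted permutation p = 0.984).

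**Figure D3:**
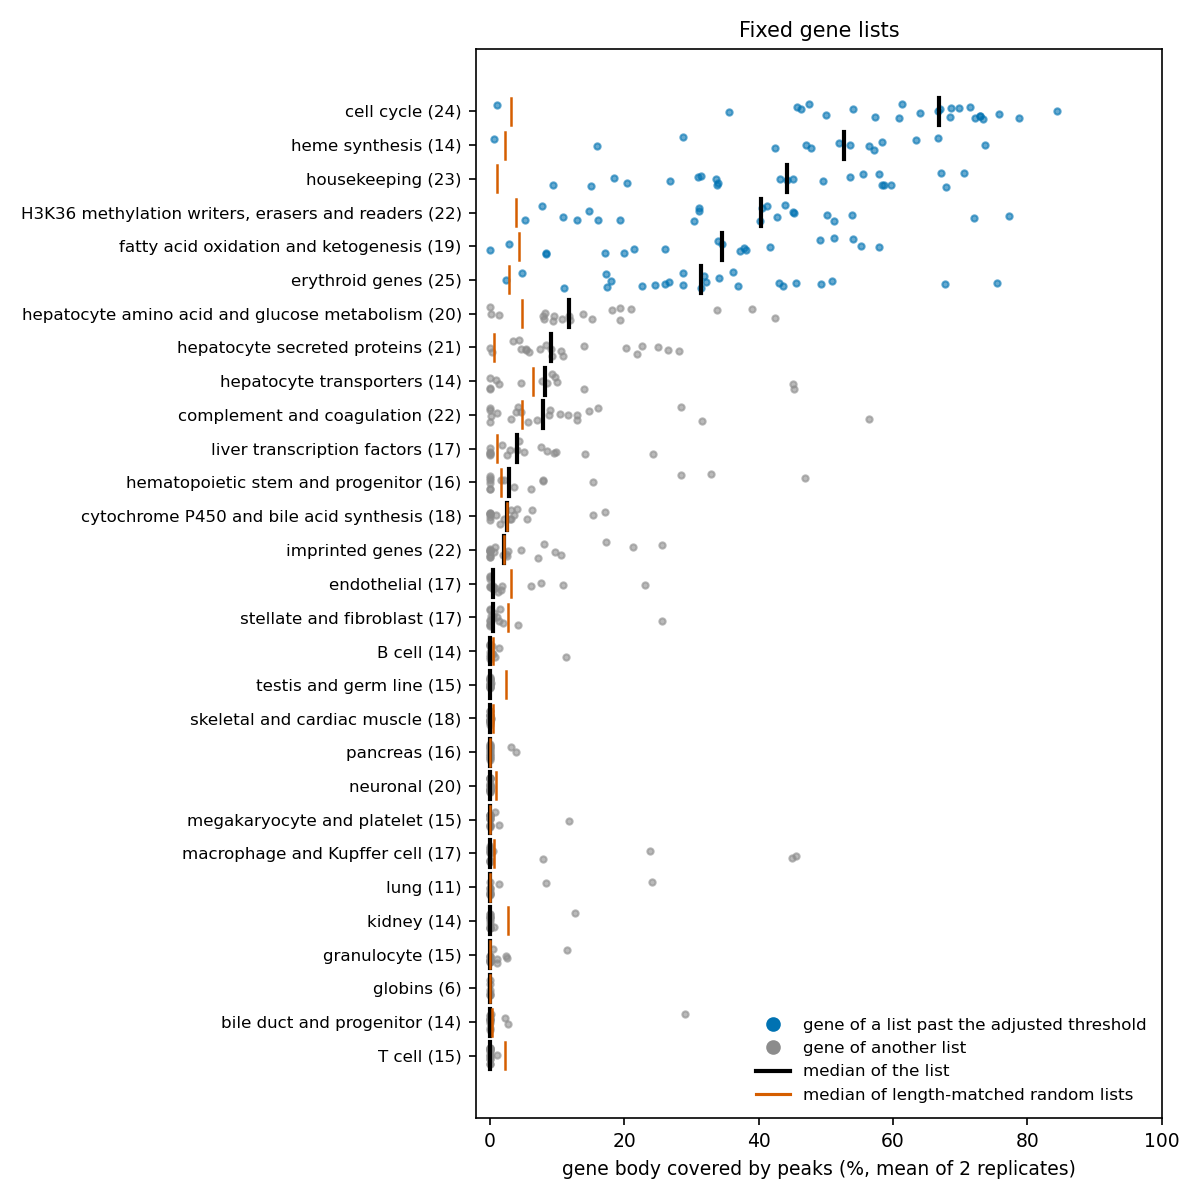
Covered share of each gene in percent, as the mean of the 2 replicates (horizontal axis), for the 29 fixed lists (rows, with the number of genes of at least 1 kb); points are genes, black bars the list medians and orange bars the medians of random lists of matched length. The cell cycle list has the highest median, 66.9%, and the lists of other tissues lie at or near 0%.

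Few markers of the other cells of a newborn liver were marked. Of 76 genes for megakaryocytes, granulocytes, macrophages, B cells and T cells, 3 were marked, all of them macrophage genes: Cd68 (45.6% ± 16.2), the iron exporter gene Slc40a1 (44.9% ± 2.61) and Hmox1, chosen after its value was seen (23.8% ± 0.599). C1qa and C1qb had 0%. The highest members of the other 4 lists were F2rl2 (11.8% ± 6.95, inside another coding gene), Lcn2 (11.5% ± 3.03), Cd79b (11.3% ± 16.0) and Tcf7 (1.09% ± 0.833). Of 16 stem and progenitor genes, Lyl1 (47.0% ± 22.6, inside another coding gene), Lmo2 (32.9% ± 8.60, 62.5% inside one) and Ikzf1 (28.5% ± 7.95, chosen after its value was seen) were marked, while Cd34 and Flt3 had 0%. Of 17 endothelial genes Stab1 was marked (23.1% ± 1.62), and of 17 stellate and fibroblast genes Ecm1 (25.6% ± 3.25). Col1a2 and Col3a1 had 0%. Among 14 bile duct genes Aqp1 was highest, at 29.1% ± 21.5, and was not marked. None of these 9 lists passed the threshold, and their adjusted permutation p-values lay between 0.787 and 1. Where the median of a list was 0%, the test could not have given a smaller p on the lower side.

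Genes of tissues not sampled served as a background. Of 94 genes of neurons, muscle, pancreas, testis, kidney and lung, 1 was marked, the lung marker Ager (24.2% ± 2.90). The highest of the others were Slc5a2 (12.7% ± 0.407) of the kidney list and Sftpb (8.43% ± 8.07) of the lung list. The best covered neuronal gene was Elavl3, at 0.203% ± 0.287. The median of each of these 6 lists was 0%, with adjusted permutation p-values between 0.3998 and 1. None of 1069 olfactory receptor genes, 276 vomeronasal receptor genes and 19 histone genes of at least 1 kb was marked. The adjusted permutation p-values of these classes were 1, 0.119 and 1. Nor was any of the 67 replication-dependent histone genes marked when the shorter ones were counted, although the cell cycle genes were covered. The 67 genes had a median length of 0.539 kb, against 16.4 kb for the cell cycle genes. Peaks were sparse within 1 kb of start sites, so this contrast cannot be told apart from gene length. The numbered zinc finger genes had 118 of 394 marked (median 10.3% against 3.06%, adjusted permutation p = 9.713e-04). Of 22 imprinted genes, Impact (25.7% ± 3.03) and Igf2r (21.3% ± 0.540) were marked, and Cdkn1c and Dlk1 had 0% (median 2.18%, adjusted permutation p = 1). In all, 8 of 34 lists passed the threshold as higher than length-matched genes and 0 as lower. The test of medians could not give a lower result where random lists also had a median of 0%, as for the globins, megakaryocytes, granulocytes, pancreas, lung, olfactory receptors and replication-dependent histones, so their p of 1 in this permutation test does not set them level with random genes. The macrophage, T cell, bile duct, neuronal, muscle, testis and kidney lists and the vomeronasal receptors also had a median of 0%, the lowest possible. Their p-values were therefore the smallest the test could give on the lower side, and do not set these lists level with random genes. At an unadjusted permutation p under 0.05 the counts were 8 higher and 1 lower, the vomeronasal receptors.

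The sixth comparison was by chromosome, in pools that held both sexes. The X chromosome stood apart from every autosome. Of 877 X-linked protein-coding genes 25 were marked (2.85%, 1.94 to 4.17), against 4877 of 20181 autosomal genes (24.2%), with single autosomes between 18.2% and 29.9%. The odds ratio was 0.0921 and the two-sided p of Fisher's exact test on genes was 6.653e-68. The mean covered share was 2.61% ± 0.159 (SD, n = 2) on X and 12.89% ± 1.34 on the autosomes. Of 163 Y-linked genes 0 were marked, and Xist had 1.71% ± 2.41. The most covered X-linked genes, chosen after their values were seen, were Hcfc1 (61.3% ± 8.30), the demethylase gene Kdm5c (50.9% ± 4.85) and Rbm3 (45.5% ± 5.11). Alas2, the erythroid enzyme of heme synthesis, which is annotated inside another coding gene, had 28.8% ± 8.48.

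**Figure D4:**
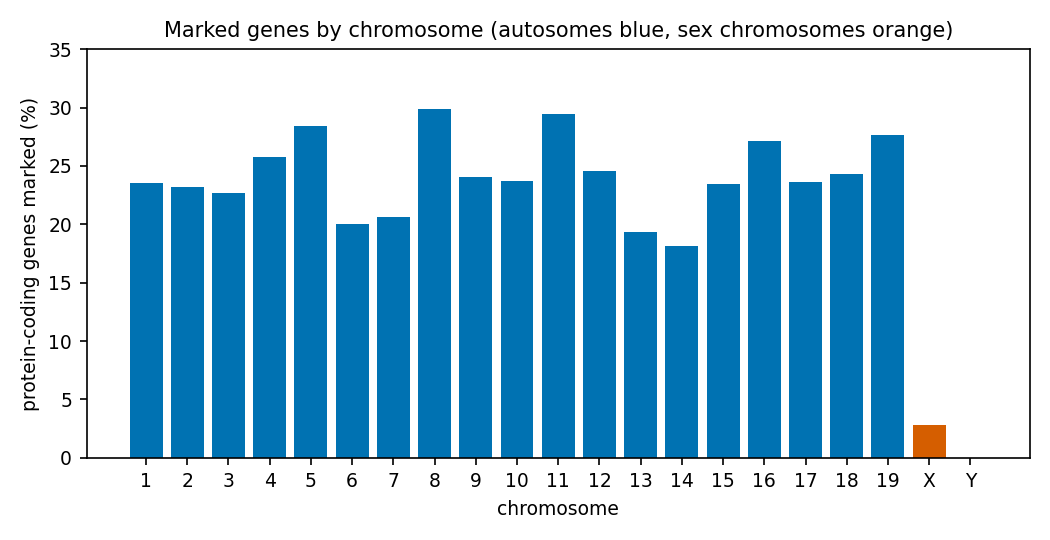
Percentage of protein-coding genes called marked (vertical axis) on each chromosome (horizontal axis); each bar is one chromosome, with autosomes in blue and sex chromosomes in orange. The autosomes lie between 18.2% and 29.9%, X is at 2.85% and Y at 0%.

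The seventh comparison was between the replicates, gene by gene, for which no test between the pools is possible. Replicate 2 covered more of most genes: 4102 of the 4902 marked genes (83.7%), with mean covered shares of 44.6% and 39.7% and a median excess of 4.72 percentage points. With equal numbers of top peaks in both lists, replicate 2 was higher in 3418 of these genes and the median excess was 2.51 points. Equal numbers did not make the covered bases equal: replicate 2 then covered 80.2 Mb and replicate 1 75.2 Mb. Across genes, which are not independent replicates, the covered shares had a Pearson r of 0.978. At the 20% minimum, 126 genes passed in replicate 1 alone and 789 in replicate 2 alone. With equal numbers of top peaks these counts were 259 and 503. The genes with the largest excess in replicate 2 were Med16 (mean of both 27.3% ± 21.9), the red cell surface gene Gypa (43.6% ± 21.8), the water channel gene Aqp1 (29.1% ± 21.5), Trim59 (35.9% ± 19.3) and Asna1 (47.1% ± 19.2). Those with the largest excess in replicate 1 were Cox7b (10.6% ± 15.0), Tent5a (13.4% ± 14.8), Jmjd7 (10.4% ± 14.7, almost wholly inside another coding gene), Rnf215 (19.9% ± 14.4) and Pced1a (20.1% ± 14.2).

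The size of this excess was then set out by gene group, in a comparison chosen after the values were seen. Its p-values rank a list against random genes within these 2 pools, are no test between the pools, and say nothing of other livers. All 18 marked erythroid genes were more covered in replicate 2, by a median of 13.3 percentage points, against 4.67 in random marked genes of the same mean coverage (adjusted permutation p = 7.999e-04 over 8 lists). Cell cycle genes were higher by 7.90 points against 4.70 (20 of 23 genes, adjusted permutation p = 0.0245). Ribosomal protein genes were higher by 1.78 points against 5.08 (31 of 55 genes, adjusted permutation p = 7.999e-04). With equal numbers of top peaks the values were lower: 10.2 points against 2.34 for erythroid genes (adjusted permutation p = 0.0016), 7.58 against 3.54 for cell cycle genes (0.0043) and 0.242 against 3.17 for ribosomal protein genes (29 of 55 genes, 0.0016). With all peaks, the other 5 gene lists lay closer to random genes, heme synthesis among them (6.46 points against 5.25, adjusted permutation p = 0.645).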

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

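Exons and introns in the 3′ part of genes were planned as an alternative before the data were seen, but the use of that value as a test of position was chosen after its result was seen, as was the test of enrichment on X, and the other tests of this part were chosen before their results.

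The pooled list holds 5576 peaks that touch no peak of either replicate list. They cover 1.10 Mb and have a median fold enrichment of 2.76, against 3.51 for the other pooled peaks. Of these peaks, 224 are in the replicated list.

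Hepatocyte genes, grouped after the list values were seen and without fatty acid oxidation and ketogenesis (13 of 19 marked) and the liver transcription factors (1 of 17), were less covered than cell cycle and housekeeping genes: 15 of 95 were marked, against 42 of 47, with mean covered shares of 10.6% and 52.2%. The size of this gap is partly set by that grouping. Beside length-matched random lists, the hepatocyte list medians were higher without passing the threshold, except for the P450 list (2.57% against 2.58%). Gene length and G+C content are argued against, because the gap was 44.1 percentage points (bootstrap interval 36.6 to 51.2) over 41 pairs matched on length and 42.9 (36.9 to 48.6) over 47 pairs matched on G+C. Enrichment that lies below the calling threshold stays open. The peaks in hepatocyte genes had a median fold enrichment of 3.32, averaged over the replicates, against 4.29 in the other genes. The ratio of the covered shares fell from 0.204 to 0.165 with a q-value of 0.01 or lower. These values cannot decide it, because the same medians per replicate, 3.34 and 3.30, recurred in other sparsely covered lists, such as the imprinted genes. The macrophage list, also sparsely covered, had 4.03 and 3.63. Whether the lower coverage reflects a smaller share of hepatocytes among the cells or less of the mark on each gene was not tested. Neither was any biological explanation.

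X-linked genes were marked less often than autosomal genes. The kinds of genes on X are argued against as the whole cause, but by 9 genes only. These X-linked members of the housekeeping, cell cycle, heme synthesis, H3K36 and ribosomal protein lists lay 32.2 percentage points below the 148 autosomal members (difference of medians -32.2, two-sided permutation p = 0.0011). The permutation was not matched on list or gene length. Of the 9, Pola1 and Abcb7 are above 113 kb, where 4.52% of all genes were marked. Repeats are argued against as the whole cause too, since autosomal genes matched on repeat share and length were marked 7.48 times as often (bootstrap interval 5.38 to 11.8). Fewer copies of X in male pups stay open: X-linked genes reached 3.11% in the pooled list, under 50% of the autosomal 11.9% and 13.8% of the single replicates, but pooling offsets copy number only for a local background, and the background used is not stated. Weaker enrichment below the calling threshold, as the silenced X of female cells would give, stays open. Peaks in X-linked genes had a median fold enrichment of 3.32, averaged over the replicates, against 3.65 in autosomal genes, a small difference. The ratio of the covered shares fell from 0.203 to 0.181 with a q-value of 0.01 or lower. These values cannot decide it, because the same medians per replicate, 3.34 and 3.30, recurred in other sparsely covered lists, such as the imprinted genes. The macrophage list, also sparsely covered, had 4.03 and 3.63. No biological explanation was tested.

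Exons were more covered than introns of the same genes. Position along the gene is argued against as the whole cause, since the gap was still 15.8 ± 0.233 percentage points (SD, n = 2) in the 3′ 50% of the gene body. It was 20.6 ± 0.176 over whole genes. Repeats in introns are argued against as the whole cause too, because over bins of 100 bases without repeat-masked bases the gap was 19.5 percentage points (bootstrap interval 18.8 to 20.2). For G+C content, bins in the 3′ part of the gene were pooled over all genes. Matched on G+C, these pooled bins had a gap of 16.0 points (15.1 to 16.9), against 19.2 points without matching. This argues against G+C content as the whole cause of the pooled gap only. Genes with long introns weigh more among the intron bins, so G+C content within the same genes stays open. No biological explanation was tested, and nucleosome density in exons stays open.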

How the results depend on the processing

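The alternatives on nested genes, the ribosomal symbols and the difference between replicates per list were chosen after the data were seen, and the others before. All 8 lists past the threshold kept their side of it under a q-value of 0.01 or lower, the replicated list, the 3′ part of genes, each replicate alone and without nested genes, and no other list joined them. The X chromosome stayed lower, with odds ratios between 0.03 and 0.155. The number of marked genes lay between 4395 and 6852 under 8 of the 9 alternatives and was 2073 with a minimum of 40%. The 4395 genes of the q-value alternative were all among the main 4902, as had to be, because that limit only removes peaks.

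Peak sharing moved with the rule. For replicate 1 it was 73.7% with 1 shared base, 38.9% with an overlap of 80%, 59.6% with a q-value of 0.01 or lower, 56.0% with equal numbers of top peaks and 53.9% with peaks joined within 1 kb. For replicate 2 these were 61.0%, 27.7%, 47.2%, 51.4% and 35.6%. The share of peak bases inside genes was 96.8% with the q-value limit, 96.9% in the replicated list and 96.0% in protein-coding genes. The gap between the last and first part of the gene was 51.8 points in the replicated list, 42.95 in genes of at least 20 kb and 16.7 in all genes, of which most are unmarked. The gap between exons and introns was 20.8 points with the q-value limit, 22.8 in the replicated list and 15.8 in the 3′ part. The cause of these shifts was not tested.

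Direction relative to random genes turned in 5 cases, none past a threshold: the P450 list in the 3′ part (median 3.42%), the stem and progenitor list without nested genes (1.92%), the imprinted list in the replicated list (0.578%) and in the 3′ part (0.512%), and the replicate difference of the H3K36 list with equal numbers of top peaks (2.75 points). No paired analysis was possible because there is a single group. Read depth is unknown, so how far it limits the weaker peaks cannot be given.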

Other observations

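The genes in this part were chosen after their values were seen. Among the writers in the H3K36 list, Setd2, which makes the trimethyl mark, had 45.1% ± 4.80 (SD, n = 2), and Nsd1, Nsd2 and Nsd3 had 50.2% ± 5.24, 45.3% ± 6.44 and 40.2% ± 4.11. The ribosomal protein genes on X were at 25.4% ± 10.6 (Rps4x), 17.3% ± 11.1 (Rpl39), 11.1% ± 6.24 (Rpl10) and 1.49% ± 2.11 (Rpl36a), against a median of 40.2% for the class.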
